A study of Osmia excavata with 6 samples.

How the data were processed

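Total RNA was extracted with TRIzol from Osmia excavata samples, and libraries were built from 1 ug of it with oligo(dT) Dynabeads, per the labels' protocols. The labels name 2 groups, control and water immersion, with 3 libraries each. They give the species in place of a tissue, so the body part, sex and age of the bees are not given in the sources used here, nor is the time between immersion and sampling. The sample titles call the immersion libraries a decocooning group. The replicates are not stated to be separate animals, so every p-value here measures only the spread between these samples.

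The deposited table lists 37061 genes of a de novo assembly, with identifiers in the style of the Trinity assembler. Each has a length in bases and, where a match was found, a protein description with its species, a Swiss-Prot name, gene ontology (GO) terms and KEGG pathways. The submitters' processing notes name cutadapt 1.9, Salmon and edgeR, without roles or options. The assembly settings, the Salmon index and the annotation thresholds are not given in the sources used here. The authors deposited estimated counts per gene, which are not all whole and sum to between 16765886 and 19953734 per library. The authors also deposited TPM values (transcript levels scaled for length and to a fixed library sum), which sum to between 999511 and 999590 per library. The deposited table gives no genome coordinates. Reads of paralogs, alleles or antisense transcripts can be split between assembled genes, so single members of multigene families are uncertain.

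Each gene was classed by the species named in its description: 11315 matched a Hymenoptera genus (7688 of them the leafcutter bee Megachile rotundata), 5562 Caenorhabditis, 6332 a mammal and 1094 another genus, and 12758 named no species. For each class's share of 1 library's counts, 95% Wilson intervals were computed. They cover counting error only.

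Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM normalization, estimateDisp, glmQLFit and glmQLFTest, treatment as the only term). Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The filter kept 17998 genes. The same fit on Hymenoptera genes alone kept 9250. That fit was added after the data had been seen to hold worm and mammal genes, and it is the one that the named genes are taken from. Values per gene are CPM of the estimated counts scaled by the TMM factors (normalised CPM), given as mean ± SD of 3 libraries. Log2 fold changes are immersion minus control, with the standard error from the quasi-likelihood test. The log2 ratio of the deposited TPM had r = 0.975 with the fitted log2 fold change over the 9250 Hymenoptera genes, and 342 genes (3.7%) had the opposite sign.

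Gene lists were patterns matched to the description columns, fixed before the data were examined together with the tests, the rule for named genes and the first group of alternatives. They cover heat shock proteins and chaperones, antioxidant enzymes, xenobiotic detoxification, immunity, serine proteases and serpins, cuticle and chitin, glycolysis, the tricarboxylic acid cycle, oxidative phosphorylation, trehalose and glycogen, fatty acid synthesis, lipid breakdown, hypoxia, water and ion transport, muscle, juvenile hormone and ecdysone, insulin signalling, the circadian clock, chemosensory proteins, phototransduction, neuropeptides and neurotransmission, storage and yolk proteins, ribosomal proteins, the proteasome, and autophagy and apoptosis. Further lists hold markers of testis, ovary, venom gland, gut, nervous system and silk gland. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, again with the correlation estimated per list, and with fry. The silk gland list had too few members and was not tested. GO and KEGG terms with 10 to 500 tested genes were tested among called genes with a one-sided Fisher exact test.

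The rule for named genes took the 10 higher and 10 lower called genes with the largest change, the 5 called genes with the highest mean, and up to 4 members per list with the smallest p. No gene was called, so the named genes come from the lists. Symbols are those of the Swiss-Prot match.

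The first group of alternatives was DESeq2 1.42.0, other normalizations (RLE, upper quartile), no filter, a filter of 5 CPM in 3 libraries, library weights in limma-voom, a fold threshold, unadjusted p, annotated genes alone, summed descriptions, the replicate number as a block, and each library left out in turn. Added after the data were seen were the Hymenoptera fit, limma-voom without weights, edgeR without its legacy option, a loess trend on transcript length (span 0.3) removed from each library, and a term for the 4 libraries with worm counts. That last term sets immersion against control 1 alone, the 1 control of those 4. It is called the within-batch fit below, although the labels give no batch. Its control arm is 1 library, assumed to vary as the others do, so its spread comes from the other libraries. It shares its libraries with the fit of all 6 and is not independent of it. Pseudocounts on TPM were not varied, since counts were tested.

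The procedure was tested on counts simulated from these libraries. For control against immersion over 17998 genes, it called 1 of 56 genes changed by a fold of 2, 16 of 53 by a fold of 4 and 25 of 48 by a fold of 8, and 2 of 14900 unchanged genes. Over the 9250 Hymenoptera genes it called 22 of 66, 65 of 67 and 65 of 66, and 18 of 8927 unchanged genes. A list raised by a fold of 2 was called in both fits, and 0 of 28 unchanged lists were. The simulated genes varied independently of each other, with no length trend and no control set apart. These rates therefore need not hold for the real libraries, and they do not measure false list calls among correlated genes. Text processing and plots used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.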

Results

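RNA was sequenced from Osmia excavata, a solitary mason bee, in 3 control libraries and 3 libraries of bees immersed in water. Immersion was used to promote emergence from the cocoon, and the comparison asks which transcripts differ with it. By their titles the immersion samples form a decocooning group, so differences from wetting and from leaving the cocoon cannot be told apart. The estimated counts came to 16765886, 18757586 and 19953734 in controls 1, 2 and 3 and to 18666554, 18562728 and 17755830 in the immersion libraries, so depth did not separate the groups. Counts were assigned to 32713 genes in control 1, to 20123 and 19775 in controls 2 and 3, and to between 32489 and 33162 in the immersion libraries.

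Hymenoptera genes held 92.9%, 94.5% and 94.4% of the counts in the controls and 92.6%, 92.6% and 92.8% in the immersion libraries. Between 10711 and 10781 of them had a count in each library, so about as many bee genes were detected in all 6. The other genes differed. Genes matching the nematode Caenorhabditis, 97.3% of them C. elegans, reached 3464 CPM in control 1 (95% Wilson interval 3436 to 3492), 0.906 in control 2 (0.566 to 1.45) and 0.201 in control 3 (0.078 to 0.516). In the immersion libraries they reached 14053 (13999 to 14106), 14978 (14923 to 15033) and 14213 (14158 to 14268) CPM. Worm vitellogenin-2, a yolk protein, stood at 119 TPM in control 1, at 0 in the other controls and at 387 to 409 TPM after immersion. Mammalian genes held 20524 CPM in control 1 (20457 to 20592), 558 in control 2 (547.6 to 569) and 331 in control 3 (323 to 339), against 11428 (11379 to 11476), 9412 (9368 to 9456) and 7122 (7083 to 7161) after immersion. The class rests on the matched species, which need not be the source of the reads. A mariner transposase matching human had 302.54 and 150.78 TPM in controls 2 and 3 and 177.42 to 408.16 TPM in the other libraries. Other abundant human matches had at most 4.21 TPM in controls 2 and 3.

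**Figure D1:**
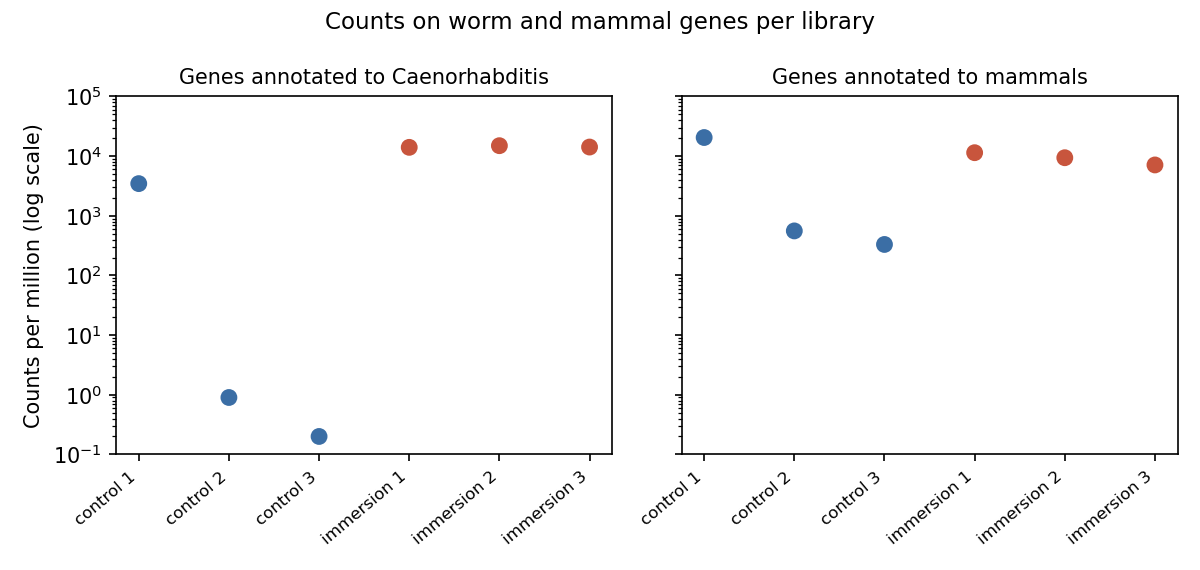
CPM (log axis) of genes matching Caenorhabditis (left) and mammals (right), 1 point per library. Worm genes stay below 1 CPM in controls 2 and 3, with 3464 CPM in control 1 and 14053 to 14978 CPM after immersion, and mammalian genes are highest in control 1 (20524 CPM).

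Among all tested genes, the first principal component held 85.8% of the variance and followed the foreign genes, with control 1 at -77, controls 2 and 3 at 210.8 and 224.2, and the immersion libraries between -129.5 and -110.5. Among Hymenoptera genes it held 75.1%, and control 1 (-12.9) lay between the immersion libraries (-38.8 to -25.8) and controls 2 and 3 (28.1 and 75.4). Across bee genes, which are not independent replicates, Pearson's r of control 1 was 0.982, 0.972 and 0.982 with the immersion libraries, 0.969 with control 2 and 0.922 with control 3. The immersion libraries had r of 0.986 to 0.991 with each other.

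**Figure D2:**
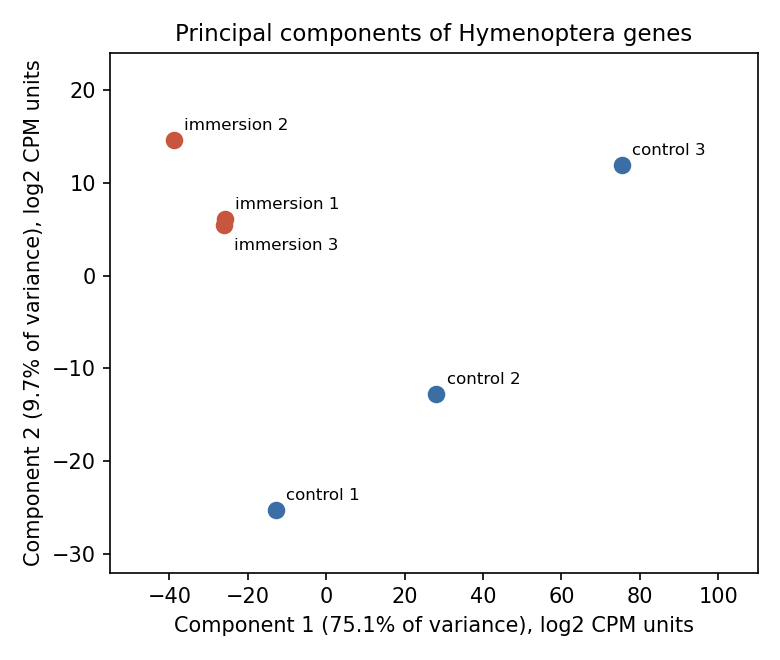
First and second principal components of log2 CPM of Hymenoptera genes, 1 point per library, in log2 CPM units. On the first component (75.1% of the variance) control 1 (-12.9) is nearer the immersion libraries (-38.8 to -25.8) than controls 2 and 3 (28.1 and 75.4).

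Among bee genes the lists of trehalose and glycogen, muscle and neuropeptides fell and those of ribosomal proteins and the proteasome rose, by camera at its preset correlation. With an estimated correlation their adjusted p were 0.545 to 0.594, and no single gene passed (0 of 9250). Of the 10 splits of the libraries into groups of equal size, 6 called 8 or more lists at the preset correlation. The real split was among them with 8, and the highest other had 13. Fell and rose, here and below, therefore describe the medians of the lists and not an established effect of immersion. The gene with the smallest p was Gbs-76A (TRINITY_DN2963_c0_g1), a subunit that directs a phosphatase to glycogen, with 132 ± 32.7 normalised CPM in controls and 36.5 ± 5.69 after immersion (SD, n = 3 each). Its log2 fold change was -1.86 ± 0.23 (SE), with an adjusted p of 0.0639 in edgeR's quasi-likelihood test. Trehalase (TRINITY_DN16281_c0_g1), which splits the blood sugar trehalose into glucose, went from 112 ± 30.0 to 40.3 ± 3.96 normalised CPM (log2 fold change -1.47 ± 0.22, adjusted p = 0.0639). OGDH (TRINITY_DN896_c0_g1), a mitochondrial enzyme of the tricarboxylic acid cycle, went from 1872 ± 71.9 to 888 ± 82.7 (-1.08 ± 0.17, adjusted p = 0.0639). In all 3 genes every immersion library lay below every control.

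In edgeR's quasi-likelihood test 0 of the 9250 Hymenoptera genes passed at an adjusted p of 0.05, and the lowest adjusted p was 0.0639. At an unadjusted p under 0.05 there were 3222 genes (34.8%), 1316 higher and 1906 lower. The groups did not overlap in 4270 (46.2%), where chance gives 10% on average over the 10 splits of the libraries. Genes vary together, with 75.1% of the variance on the first principal component. A single split can therefore hold far more than 10% without an effect of treatment. DESeq2 called 2024 genes (686 higher, 1338 lower) and limma-voom with library weights 6373 (3359 higher, 3014 lower), whereas limma-voom without weights and edgeR without its legacy option called 0. Without control 1 edgeR called 4912 genes, of which 1990 were also called by DESeq2, and without control 3 it called 362. Control 1 is the only control with more than traces of worm and mammal reads. Without it, here and below, immersion cannot be told apart from whatever brought those reads. The removal of length trends gave 26, and the within-batch fit called 1. That fit has control 1 as its only control and takes its spread from the other libraries. It shares all of its libraries with the fit of 6, so the values from it below are no independent test (r = 0.605 between the fold changes of the 2 fits).

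Among all 17998 genes edgeR also called 0 (lowest adjusted p 0.163), with 4057 at an unadjusted p under 0.05 (2026 higher, 2031 lower). The groups did not overlap in 8572 (47.6%, against the same average of 10%), and these genes vary together too. Here 962 of the 2026 higher genes matched Caenorhabditis, whose 3190 tested genes had a median log2 fold change of 3.49 and no overlap in 3186. Counts by the other tools were 3332 in DESeq2, 12199 in limma-voom with weights, 4676 in limma-voom without them and 3068 in edgeR without its legacy option. Without control 1 edgeR called 12559 genes. Worm genes can enter the within-batch fit too, since they held 3464 CPM in control 1 and 14053 to 14978 CPM after immersion.

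Genes of trehalose and glycogen metabolism fell, with a median log2 fold change of -0.51 over 36 bee members, 31 of them negative (camera adjusted p = 6.09e-07). With an estimated correlation the adjusted p was 0.545. Of the members, 0 passed over all genes and 16 passed when adjusted over the list alone, all lower. Besides Gbs-76A and trehalase they include a Tret1-like trehalose transporter (TRINITY_DN2126_c0_g3), with 7.82 ± 1.21 normalised CPM in controls and 2.47 ± 0.41 after immersion, and sgg (TRINITY_DN1404_c1_g1), the kinase that restrains glycogen synthase, with 338 ± 124 and 116 ± 10.6. In the within-batch fit the list's median was -0.30 (adjusted p = 3.05e-08), and Gbs-76A, trehalase and sgg stood at -1.38, -0.99 and -0.88.

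The neighbouring energy pathways did not pass. The tricarboxylic acid cycle had a median of -0.13 over 51 genes (adjusted p = 0.13) and glycolysis one of -0.22 over 25 (adjusted p = 0.105), with 9 and 6 members lower when adjusted over the list alone and 0 over all genes. Citrate synthase (TRINITY_DN3096_c0_g1), which opens the cycle, averaged 3235 ± 193 normalised CPM in controls and 1592 ± 191 after immersion. A hexokinase by its Swiss-Prot match, Hex-t2 (TRINITY_DN281_c0_g1), had 909 ± 132 and 428 ± 45.1. Pfk (TRINITY_DN784_c0_g1), the main control point of glycolysis, had 678 ± 67.0 and 383 ± 42.1. Both lists had negative medians in the within-batch fit, -0.26 and -0.23. The tricarboxylic acid cycle passed without control 3 (camera adjusted p = 0.0218 at the preset correlation). With an estimated correlation both lists had a camera adjusted p of 0.545 in the fit of all 6 libraries.

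Muscle contraction proteins fell, with a median log2 fold change of -0.68 over 83 genes, 67 of them negative (camera adjusted p = 1.76e-07). The adjusted p with an estimated correlation was 0.545. Adjusted over the list alone 36 members were lower and 3 higher, against 0 over all genes. Zasp52 (TRINITY_DN3299_c0_g1), described as titin in the table and by its symbol a protein of the muscle Z disc, had 2668 ± 726 normalised CPM in controls and 903 ± 167 after immersion (log2 fold change -1.56 ± 0.26). A muscle actin (TRINITY_DN4483_c0_g1), from a family with near-identical members, had 55.7 ± 22.3 and 17.0 ± 4.21. On the other side a sarcoplasmic calcium-binding protein (TRINITY_DN22558_c0_g2) had 14.8 ± 2.44 and 31.8 ± 1.70. The within-batch median was -0.26 (adjusted p = 0.000122), with Zasp52 at -1.16, and the median was -0.14 with length trends removed and -0.42 without control 3.

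Neuropeptides and neurotransmission fell, with a median of -0.32 over 117 genes, 87 of them negative (camera adjusted p = 0.00039, and adjusted p = 0.545 with an estimated correlation). Adjusted over the list alone 15 members were lower, against 0 over all genes. Both acetylcholine receptor subunits named by the rule, Chrna3 (TRINITY_DN5328_c0_g1) and CHRNA3 (TRINITY_DN5778_c0_g1), had low counts after immersion: 34.5 ± 13.7 normalised CPM in controls against 6.20 ± 1.88, and 12.9 ± 6.33 against 1.75 ± 0.84. Octbeta2R (TRINITY_DN3420_c0_g1), a receptor for the arousal transmitter octopamine, had 93.8 ± 22.3 and 45.5 ± 3.77. The list's median was -0.11 in the within-batch fit (adjusted p = 0.0203) and -0.19 without control 3. Nervous system and eye markers were chosen in case the samples held unequal shares of that tissue, a share that was not measured. They had a median of -0.29 and did not pass (camera adjusted p = 0.0957). In edgeR 13 were lower and 2 higher of 35 members at an unadjusted p under 0.05. Of all 9250 bee genes 34.8% reached that p (1906 lower, 1316 higher).

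Water and ion transport fell by a smaller amount, with a median of -0.22 over 85 genes, 53 of them negative (camera adjusted p = 0.019, and adjusted p = 0.545 with an estimated correlation). It had 4 lower members adjusted over the list alone and 0 over all genes. A chloride channel by its Swiss-Prot match, glc-1 (TRINITY_DN3844_c0_g1), had 79.4 ± 13.6 normalised CPM in controls and 33.3 ± 7.28 after immersion. A subunit of the sodium pump, nrv2 (TRINITY_DN3541_c1_g1), had 277 ± 56.5 and 140.2 ± 13.7. The median was -0.13 in the within-batch fit (adjusted p = 0.0121), -0.07 with length trends removed (adjusted p = 0.0483) and -0.14 without control 3.

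Juvenile hormone and ecdysone genes fell, with a median of -0.44 over 56 genes, 39 of them negative (camera adjusted p = 0.0225, and adjusted p = 0.545 with an estimated correlation). No member passed over the list alone (0) or over all genes (0). At an unadjusted p under 0.05 edgeR gave 16 of the 56, 13 lower and 3 higher. Of all 9250 bee genes 34.8% reached that p (1906 lower, 1316 higher). The moulting hormone's response genes br (TRINITY_DN1981_c0_g1) and E75 (TRINITY_DN388_c1_g4) had 38.8 ± 4.97 and 89.8 ± 36.4 normalised CPM in controls and 18.6 ± 3.69 and 33.5 ± 7.29 after immersion. The list did not pass in the within-batch fit (median -0.04, adjusted p = 0.453) or without control 3 (median -0.25, adjusted p = 0.0552).

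Xenobiotic detoxification enzymes fell, with a median of -0.22 over 94 genes, 66 of them negative (camera adjusted p = 0.029, and adjusted p = 0.545 with an estimated correlation). No member passed over the list alone (0) or over all genes (0). At an unadjusted p under 0.05 edgeR gave 22 lower and 3 higher of the 94. Of all 9250 bee genes 34.8% reached that p (1906 lower, 1316 higher). Cyp4g15 (TRINITY_DN2486_c0_g3), a cytochrome P450, had 103 ± 14.8 normalised CPM in controls and 54.7 ± 11.3 after immersion. The call was lost without control 1 (adjusted p = 0.0669) and without immersion library 3 (adjusted p = 0.0555), and the within-batch median was -0.17 (adjusted p = 0.0448).

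Cytosolic ribosomal proteins rose, with a median of 0.56 over 77 genes, 71 of them positive (camera adjusted p = 1.76e-07, and adjusted p = 0.594 with an estimated correlation). No member passed over the list alone (0) or over all genes (0). At an unadjusted p under 0.05 edgeR gave 21 higher and 0 lower of the 77. Of all 9250 bee genes 34.8% reached that p (1316 higher, 1906 lower). RpL3 (TRINITY_DN1772_c0_g1) had 977 ± 127 normalised CPM in controls and 1500 ± 62.4 after immersion, and RpL5 (TRINITY_DN3589_c0_g1) had 730.0 ± 199 and 1238 ± 64.7. The list's within-batch median was 0.42, and with 1 library left out the median lay between 0.31 (without control 3) and 0.86 (without control 2). Its members had a median length of 912 bases, and with length trends removed the list's median was 0.31. Proteasome genes, which encode the complex that degrades tagged proteins, rose with a median of 0.66 over 53 genes, 44 of them positive (camera adjusted p = 6.95e-07, and adjusted p = 0.545 with an estimated correlation). They too had 0 members past the threshold over the list alone and over all genes, with 29 higher and 2 lower at an unadjusted p under 0.05 in edgeR. Dox-A2 (TRINITY_DN9762_c0_g1) had 93.2 ± 20.7 and 154 ± 6.73 normalised CPM, and PSMA3 (TRINITY_DN25814_c0_g1) had 49.5 ± 11.1 and 83.7 ± 11.3. Their within-batch median was 0.29 (adjusted p = 0.000141).

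**Figure D3:**
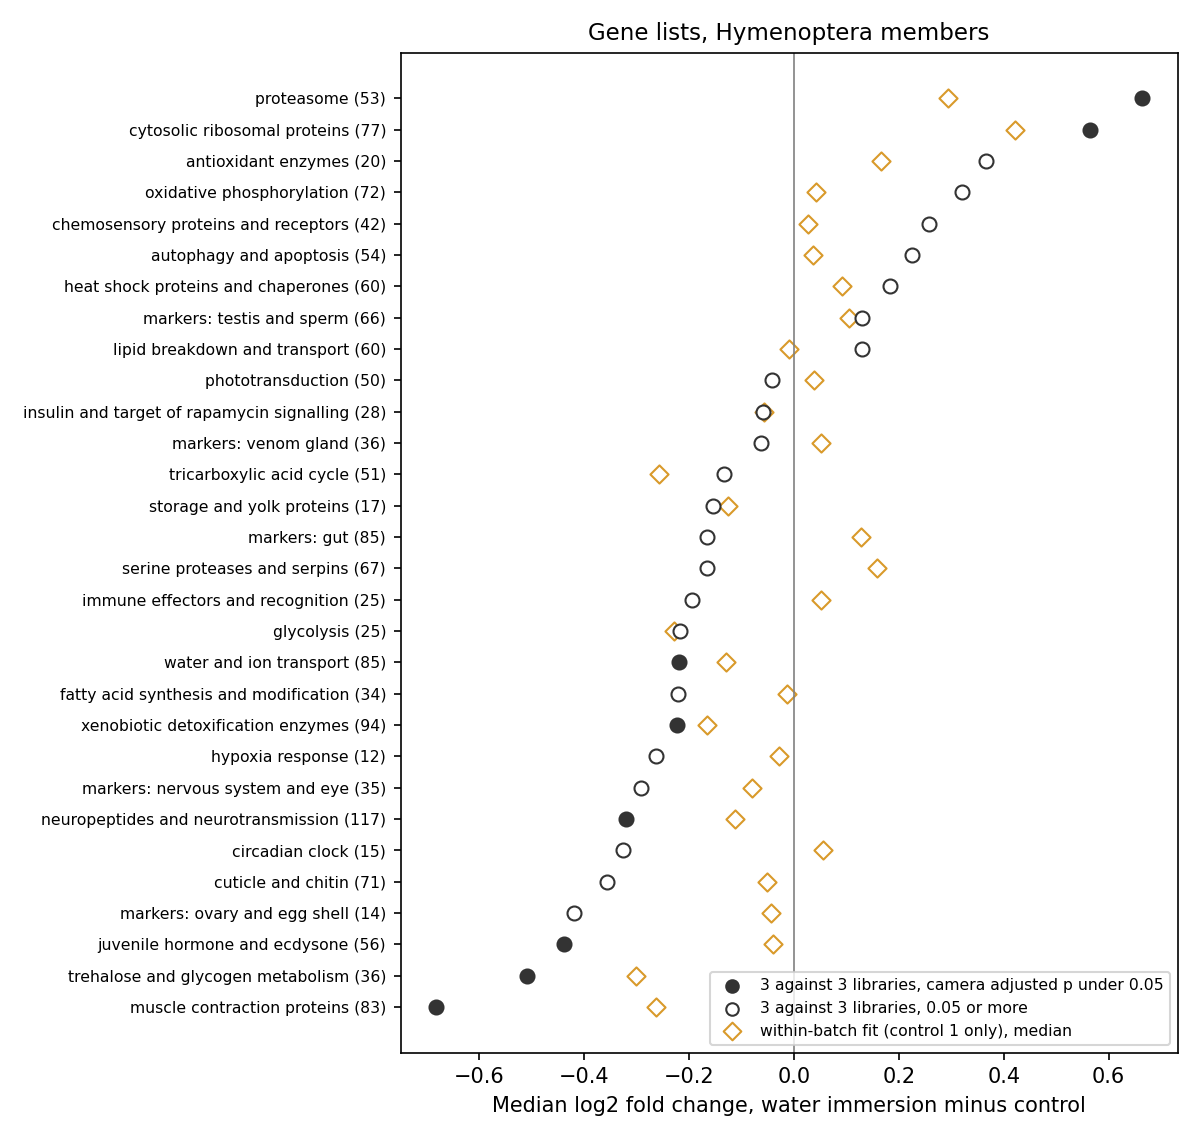
Median log2 fold change (immersion minus control) of the gene lists among Hymenoptera genes, with all 3 controls (circles, filled where camera passed at its preset correlation) and in the within-batch fit against control 1 alone (open diamonds, medians only), member number in brackets. Muscle (-0.68 and -0.26) and trehalose and glycogen (-0.51 and -0.30) are on the lower side in both, ribosomal proteins (0.56 and 0.42) and proteasome (0.66 and 0.29) on the higher side.

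The calls thus numbered 8 of 30 lists, 2 higher and 6 lower. None (0) passed with an estimated correlation or with fry. In the 8 lists the estimated correlation lay between 0.0145 (water and ion transport) and 0.69 (ribosomal proteins), above the preset 0.01. Since 6 of the 10 splits of the libraries called 8 or more lists, the number of calls does not set the real split apart. Of the 8 calls, 7 passed without control 1 and 8 after removal of the trend on transcript length, all at the preset correlation. Without control 1, treatment and the worm and mammal reads part the libraries alike, so those 7 are no check on a batch.

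**Figure D4:**
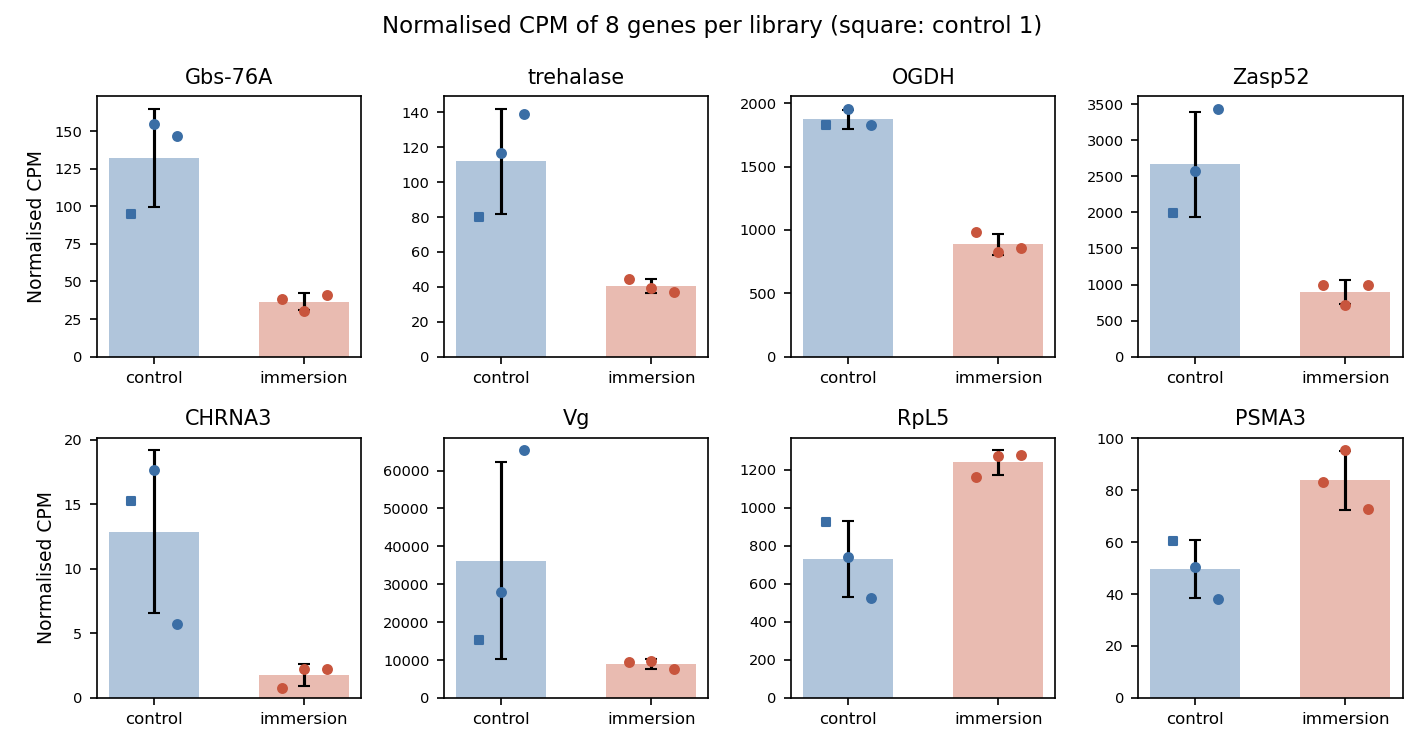
Normalised CPM of 8 named bee genes, with bars for the means of 3 libraries, error bars for the SD and points for the libraries (square, control 1). For Gbs-76A, trehalase and Zasp52 the immersion libraries lie below all 3 controls, and control 1 is the control nearest to them.

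The other lists did not pass in the Hymenoptera fit. Cuticle and chitin had a median of -0.36 (adjusted p = 0.0571), and it passed without control 1 (adjusted p = 0.0397), without immersion library 2 (0.0367), without immersion library 3 (0.0489), with upper-quartile scaling (0.0395), with summed descriptions (0.0235) and with length trends removed (0.000136), but not in the within-batch fit (median -0.05, adjusted p = 0.735). In it resilin (TRINITY_DN855_c0_g1), the elastic protein of wing hinges, had 146 ± 68.7 normalised CPM in controls and 56.6 ± 14.3 after immersion. Storage and yolk proteins had a median of -0.16 (adjusted p = 0.0755), 5 lower members adjusted over the list alone, and a call without control 3 (adjusted p = 0.0211), with summed descriptions (0.0231) and with length trends removed (0.0189). Vitellogenin, Vg (TRINITY_DN7540_c0_g1), the main egg yolk protein, had 36240 ± 26050 normalised CPM in controls and 8930 ± 1230 after immersion. By TPM its groups overlapped, with 4961 in control 1 and 5482 to 7243 after immersion. Heat shock proteins (0.18, adjusted p = 0.13), antioxidant enzymes (0.37, 0.13), oxidative phosphorylation (0.32, 0.139), chemosensory proteins (0.26, 0.192), autophagy and apoptosis (0.23, 0.333) and lipid breakdown (0.13, 0.578) had positive medians. Oxidative phosphorylation passed without control 2 (0.52, adjusted p = 0.00425), whereas without control 3 its median was -0.06 (adjusted p = 0.302). Insulin signalling (-0.06, adjusted p = 0.326), phototransduction (-0.04, 0.588), serine proteases (-0.17, 0.541), immunity (-0.19, 0.283), fatty acid synthesis (-0.22, 0.299), hypoxia (-0.26, 0.244) and the circadian clock (-0.33, 0.487) had negative ones. Serine proteases had a median of the opposite sign in the within-batch fit (0.16), and immunity passed with length trends removed (-0.23, adjusted p = 0.0118). All these calls used camera's preset correlation. With an estimated correlation over all 6 libraries, cuticle and chitin and storage and yolk proteins each had an adjusted p of 0.545. Oxidative phosphorylation then had 0.787, serine proteases 0.8 and immunity 0.608.

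Marker lists of organs that the samples could hold in unequal shares also did not pass. Their medians were -0.42 for ovary (adjusted p = 0.105), -0.29 for nervous system and eye (0.0957), -0.17 for gut (0.341), -0.06 for venom gland (0.875) and 0.13 for testis (0.341). Gut markers had a positive median in the within-batch fit (0.13). With an estimated correlation their camera adjusted p was 0.778 in the fit of all 6 libraries.

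Among all genes camera called 12 of 30 lists, and the foreign members entered them. Camera sets a list against the other tested genes, here with 3190 worm genes at a median log2 fold change of 3.49. A list made up mostly of bee genes can thus be called lower for not rising with them. Cytosolic ribosomal proteins (0.53, adjusted p = 3.16e-06), proteasome (0.80, 4.24e-06), oxidative phosphorylation (0.80, 0.000173), heat shock proteins (0.49, 0.00146), lipid breakdown (0.64, 0.0159), autophagy and apoptosis (0.48, 0.0273) and antioxidant enzymes (0.52, 0.0297) rose, each with an adjusted p of 0.82 with an estimated correlation. These 7 medians lay between 1.69 (lipid breakdown) and 7.57 (ribosomal proteins) without control 1 and between 0.14 (ribosomal proteins) and 0.45 without control 3. With length trends removed they lay between -0.30 (ribosomal proteins) and 0.22 (lipid breakdown), with heat shock proteins at 0.03, oxidative phosphorylation at 0.04 and proteasome at 0.06. Calls were lost by antioxidant enzymes without control 2 (adjusted p = 0.187), without control 3 (0.228) and with length trends removed (0.107), by autophagy and apoptosis without control 2 (0.0654), without control 3 (0.0609) and with summed descriptions (0.0711), and by oxidative phosphorylation without control 3 (0.0609). Trehalose and glycogen (-0.31, 0.000172), neuropeptides (-0.21, 0.000172), juvenile hormone and ecdysone (-0.40, 0.000632), detoxification (-0.15, 0.00146) and nervous system markers (-0.13, 0.00371) fell, with an adjusted p of 0.202, 0.202, 0.403, 0.241 and 0.202 with an estimated correlation. With length trends removed their medians lay between -0.61 (detoxification) and -0.42 (nervous system markers), and trehalose and glycogen (adjusted p = 0.17) and nervous system markers (0.0894) lost their calls. The mean log2 fold change of trehalose and glycogen (0.25) and of detoxification (0.10) had the opposite sign to their medians. Among bee genes alone nervous system markers did not pass (camera adjusted p = 0.0957). Of the ribosomal members 192 of 269 were not Hymenoptera, of oxidative phosphorylation 130 of 202 and of heat shock proteins 92 of 152. Lists not called here passed under some alternatives, glycolysis without control 1 (adjusted p = 0.000135) and with length trends removed (0.0157), the tricarboxylic acid cycle likewise (0.0017 and 0.0169), and muscle without immersion library 3 (0.012). In the within-batch fit cuticle and chitin had a median of 0.15, with 36 of its 111 members matching Caenorhabditis. Upper-quartile scaling moved the median of all genes by -0.12.

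No annotation term was enriched in either fit (0), since no gene was called. At an unadjusted p under 0.05 and an absolute log2 fold change of at least 1, a threshold without correction for the number of genes, the Hymenoptera genes gave 41 terms by Fisher's exact test, 37 among 473 lower genes and 4 among 167 higher genes. Lower genes held 30 of 124 with sequence-specific DNA binding against 7.6 by chance (adjusted p = 9.54e-08), 15 of 43 of motor neuron axon guidance against 2.7 (1.18e-05) and 11 of 32 with chitin binding against 2 (0.000409). Higher genes held 6 of 43 of the KEGG proteasome against 0.9 (adjusted p = 0.0183) and 11 of 155 of the nucleolus against 3.4 (0.0298). Fisher's test took no account of correlation between genes or of transcript length. Fold changes were positive for 69.6% of the shortest class of bee genes and 11.5% of the longest. With length trends removed 26 genes were called and 0 terms. Without control 1 there were 223 terms, without control 3 there were 11, and in the within-batch fit 0.

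The fold changes of bee genes went with transcript length. From the shortest class (212 to 1348 bases) to the longest (4699 to 27585 bases), medians over classes of equal size were 0.41, 0.41, 0.19, -0.14 and -0.56. Across the 9250 genes r of log2 fold change with log2 length was -0.42, and the log2 ratio of control 2 to control 3 had r = -0.45 with it. The median length was 912 bases in the ribosomal list, 1407 in the proteasome list and 5453 in the muscle list, against 2561 over all tested bee genes. With the length trend removed their medians went from 0.56 to 0.31, from 0.66 to 0.45 and from -0.68 to -0.14, with camera adjusted p of 0.00242, 0.000182 and 0.00378.

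**Figure D5:**
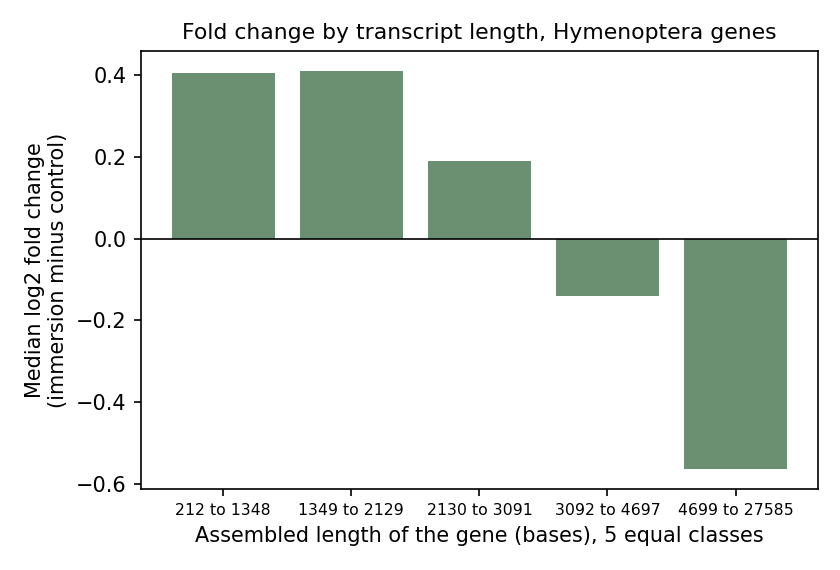
Median log2 fold change of Hymenoptera genes (immersion minus control) in 5 equal classes of assembled length in bases, 1 bar per class. The median goes from 0.41 in the shortest class to -0.56 in the longest.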

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

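The tests in this part were chosen after the result was seen, except the correlations of the worm and mammal profiles of control 1 with those of the immersion libraries. Genes matching Caenorhabditis, which lie outside the comparison of bee genes, held 14052.6, 14977.8 and 14212.8 CPM in immersion libraries 1, 2 and 3, above the highest control (3464.1 CPM in control 1).

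Worm and mammalian genes were both present in control 1 and the immersion libraries and nearly absent from controls 2 and 3. Worms on the bees or in the water would bring no mammalian RNA, yet mammalian genes held at least 7122.2 CPM in each immersion library against 558.2 and 330.9 CPM in controls 2 and 3, which argues against worms as the whole source. Reads from 1 worm source that reached all 4 libraries are a candidate source. Over 3267 worm genes control 1 had r = 0.91 with the immersion mean, where the lowest r between immersion libraries was 0.962. No profile of a separate worm source was compared, so this r cannot tell 1 source from several. The mammalian profile had r = 0.682 over 2320 genes, with r down to 0.562 between immersion libraries, so it stays open whether 1 mammalian source fed the 4. Single mammalian genes were unlike between them: mouse Myl2, a heart myosin chain, stood at 0 TPM in control 1 and at 119.68, 50.76 and 52.33 TPM after immersion, and rat Col3a1 at 123.13 TPM in control 1 and at 1.79 to 2.29 TPM after immersion (chosen after their values were seen).

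In bee genes control 1 lay nearer the immersion libraries than controls 2 and 3 did. On a scale from 0 (mean of controls 2 and 3) to 1 (immersion mean), its median position over 4051 genes was 0.757 (quartiles 0.596 and 0.909), whereas carry-over of immersion reads would place it near the ratio of worm CPM, 0.24. After removal of the length trends it was 0.752 (quartiles 0.569 and 0.922), so those trends do not account for it. A wrong label stays open: control 1 lay beyond the immersion libraries on the control side in 70.1% of these genes, and each immersion library lay beyond the other two in 42.4%, 10.9% and 46.7%. A preparation batch cannot be told apart from the state of these bees either, since only 1 control shares the worm genes, and age, sex and body part were not given or tested.

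Fold changes of bee genes were lower for longer transcripts. Differences in RNA or library quality may contribute, since the same trend appeared between controls 2 and 3, where no treatment differed (absolute r 0.451, against r = -0.42 for the fold changes). A biological preference for short transcripts was not tested. All 8 lists called among bee genes were called at the preset correlation after its removal too, although their medians came closer to 0 (muscle from -0.68 to -0.14). With an estimated correlation 0 lists passed even before removal, so the calls cannot settle whether the trend is their whole cause.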

How the results depend on the processing

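Chosen after the data were seen were the Hymenoptera fit, limma-voom without weights, edgeR without its legacy option, the removal of length trends and the within-batch term. The pseudocount alternative was not run, since counts were tested. The replicate numbers are not said to pair the samples. Deviations of same-numbered libraries from their group means had r = -0.03, -0.19 and 0.18 over all genes and -0.15, 0.14 and 0.16 over bee genes. Deviations within a group are tied to each other through its mean, so these values cannot settle pairing. With the replicate block edgeR called 0 genes in both, and camera 13 and 10 lists, the 10 being the 8 below with cuticle and chitin (adjusted p = 0.0347) and storage and yolk proteins (0.0347).

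Over all genes edgeR called 0. Worm genes can enter the counts below, also with the within-batch term, since they were higher after immersion than in control 1. Counts of called genes were 3332 with DESeq2 (2185 higher, 1147 lower), 12199 with library weights in voom (8620, 3579), 4676 with limma-voom without weights (3623, 1053), 3068 without the legacy option (2361, 707), 2259 with the within-batch term (1754, 505), and 1908 at an unadjusted p under 0.05 with a log2 fold change of at least 1 (1210, 698). Leaving out 1 library gave 0 to 12559, the highest without control 1, and the other alternatives gave 0. The 12 lists became 1 with the within-batch term, 0 with an estimated correlation and 2 with fry, and otherwise 9 to 15. The 0 enriched terms became 75 at the unadjusted p, 288 with the within-batch term and 0 to 678 without 1 library.

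Over bee genes edgeR also called 0. The count was 2024 with DESeq2 (686, 1338), 6373 with library weights (3359, 3014), 26 with length trends removed (all lower), 1 with the within-batch term, 822 at the unadjusted p (226, 596), and 0 to 4912 without 1 library (4912 without control 1, 362 without control 3). The 8 lists became 0 with an estimated correlation and 0 with fry, and otherwise numbered 8 to 11. The 0 terms became 41 at the unadjusted p and 0 to 223 without 1 library. The cause was not tested. The weights of voom for controls 1, 2 and 3 were 0.083, 2.61 and 0.48 over all genes and 0.20, 6.44 and 0.16 over bee genes.

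Lists called with or without an alternative whose median and test direction both turned were, over all genes, chemosensory proteins with length trends removed (-0.85) and antioxidant enzymes within batch (-0.22), and over bee genes serine proteases (0.16) and gut markers (0.13) within batch. The median alone turned over all genes with length trends removed (ribosomal -0.30, antioxidant -0.02, venom gland -0.78) and without control 1 (detoxification 0.01, gut markers 0.06). Of the 69 named genes, 68 passed without control 1, 41 without control 3 and 3 with length trends removed. Of all bee genes 4912 of 9396, 362 of 9362 and 26 of 9250 passed in these settings. The named genes were chosen for their small p in the same libraries, so their passing is no independent check. For the 68, immersion cannot be told apart from the presence of worm and mammal reads. Depth was not varied. Simulated changes by a fold of 4 were recovered in 65 of 67 bee genes and 16 of 53 of all genes, and by a fold of 2 in 22 of 66 bee genes. Simulated genes varied independently, so these shares need not hold for the real libraries.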

Other observations

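The tests of this part, counts over other splits of the samples, were set down after the results had been seen. The genes below come from the rule for named genes unless stated, and none passed over all bee genes, with adjusted p from 0.0639 to 0.118 in edgeR's quasi-likelihood test. Of the genes of heat shock proteins, a list that did not pass (adjusted p = 0.13), 1 matching l(2)efl (TRINITY_DN120_c0_g1) had 4571 ± 235 normalised CPM in controls and 2292 ± 532 after immersion (SD, n = 3 each), and another (TRINITY_DN27543_c0_g1) had 52.2 ± 12.2 and 99.02 ± 16.5. HSPB1 (TRINITY_DN340_c0_g1) had 1371 ± 208 and 789 ± 32.2. Among antioxidant enzymes, Sod (TRINITY_DN6697_c0_g2), which removes superoxide, had 291 ± 55.1 and 435 ± 49.7, whereas Cat (TRINITY_DN17236_c0_g3), which breaks down hydrogen peroxide, had 371 ± 115 and 226 ± 5.42. In insulin signalling, foxo (TRINITY_DN763_c4_g1), the transcription factor that insulin restrains, had 219 ± 54.7 and 107 ± 16.2, and chico (TRINITY_DN2931_c1_g1), the substrate of the insulin receptor, had 143 ± 40.5 and 68.5 ± 12.6.

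Among secreted and sensory proteins, a pheromone-binding protein (TRINITY_DN16214_c0_g1) had 105 ± 26.3 normalised CPM in controls and 197 ± 53.0 after immersion. The transmembrane protease Tmprss3 (TRINITY_DN1137_c0_g1) had 108 ± 4.42 and 207 ± 19.2, and its log2 fold change against control 1 alone was 1.00. A venom allergen 3-like protein (TRINITY_DN26_c0_g3) had 259 ± 9.24 and 426 ± 27.6. A beta-glucan-binding protein, GRP (TRINITY_DN10799_c0_g1), which recognises fungal cell walls, had 307 ± 183 and 72.1 ± 6.11. Apolipophorins (TRINITY_DN1986_c0_g2), the lipid carrier of the blood, had 8318 ± 5119 and 2375 ± 121. The clock gene per (TRINITY_DN1025_c0_g1) had 122 ± 15.9 and 89.8 ± 8.93, and its log2 fold change went from -0.44 to 0.23 with length trends removed.

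Control 1 stood apart in a few bee genes, chosen after their values were seen. A second gene for translationally controlled tumour protein (TRINITY_DN1214_c0_g1) had 5 counts in control 1 and 1867 to 4031 in the other libraries, and was the 1 gene called in the within-batch fit (log2 fold change 8.74 ± 0.60, adjusted p = 0.0193 in edgeR). The better covered gene Tctp (TRINITY_DN2478_c0_g1) had 5075.6 TPM in control 1 and 4890.9 to 5462.3 TPM after immersion, against 3221.8 and 1489.9 TPM in controls 2 and 3. Chymotrypsin-1 (TRINITY_DN3708_c0_g1), a gut protease, had 72.4 TPM in control 1 and 443 to 1187 TPM elsewhere.

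The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The count of called genes was 0 in the real split and in all 10, over all genes and over bee genes. The real split called 12 lists over all genes, with 19 as the highest other and 4 splits at 12 or more. Over bee genes it called 8 lists, with 13 as the highest other and 6 splits at 8 or more. At an unadjusted p under 0.05 the real split gave 3222 bee genes, with 912 as the highest other, so 1 split reached that count.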
